A study of Drosophila melanogaster with 12 samples.

How the data were processed

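RNA sequencing was done on heads of Drosophila melanogaster, brain included. Control flies carried UAS-dicer2 and the tim(UAS)-Gal4 driver, which is active in clock cells. Knockdown flies carried in addition a UAS hairpin against dppil4, the gene CG5808. The flies were kept in cycles of 12 h of light and 12 h of darkness and were collected on day 4 at ZT8, in the light phase, and at ZT16, in the dark phase. Each of the 4 groups of genotype and time held 3 libraries. Per the labels, RNA was extracted with QIAzol and the libraries were made with the TruSeq Stranded mRNA kit.

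Per the submitters' processing notes, the authors aligned the reads with STAR 2.6.0c to the dm6 genome and estimated expression per transcript with RSEM 1.3.1. The deposited values are of 3 kinds: expected counts, which the deposited table holds as whole numbers, FPKM and TPM. FPKM and TPM were computed by the authors, and FPKM was not used here beyond a check of the units. The table held 35536 transcripts of 17816 genes, including 118 rRNA genes, which stayed in the analysis. The strand setting of the counting was not given in the sources used here, so a value of a gene that overlaps another on the opposite strand, and of an antisense RNA, can hold reads of its neighbour. Column names of the control ZT16 libraries differed from the library names in the labels by the digit 2 and were matched by time and number. All 12 libraries were matched to a group.

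Expected counts were summed over the transcripts of each gene. Gene counts were fitted with edgeR 4.0.16 in R 4.3.3, in 1 model of 4 group means over all 12 libraries with 8 residual degrees of freedom. Genes were filtered with filterByExpr at its minimum count of 10, factors were from TMM, and the robust quasi-likelihood F test was used. P values were adjusted with the Benjamini-Hochberg method, and a gene was called changed at an adjusted p under 0.05. The 6 comparisons were knockdown against control at ZT8, at ZT16 and over both times, ZT16 against ZT8 in control and in knockdown, and the interaction, which is the knockdown effect at ZT16 minus that at ZT8. Gene values are log2 fold changes with their standard error, and levels are CPM, the counts divided by the scaled library size times 1e6, with the SD of 3 libraries. The standard error was computed back from the test, as the absolute log2 fold change divided by the square root of F. It is rough for genes with few reads in 1 group. Where a group had 0 reads, the fold is a bound computed from 3 counts over the group. Bounds and counting intervals at 95% cover counting error only, since PCR copies are not independent molecules.

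Lists of genes were fixed in 34 groups that covered the clock, neuron, glia, eye, antenna, muscle, fat body, immune, stress, metabolic and RNA processing genes, and markers of other tissues. Each list was tested against all other tested genes with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way and compares them with no other genes, were alternatives. Transcript usage was tested with the F test of diffSplice in limma on voom values of transcript counts, and only clock genes are named from it. For diffSplice the test was settled on simulated counts: the Simes test was tried first, then the F test and diffSpliceDGE, and the F test was kept because it made the fewest false calls (8, against 21 and 46). Pearson and Spearman coefficients are across genes, which are not independent replicates.

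These genes were named: CG5808 and 8 core clock genes in every comparison, the 8 largest rises and the 8 largest falls at each time, the 5 largest rises and the 5 largest falls with time in control and in the interaction, up to 4 members of each called list and up to 2 of the others. The largest changes needed a mean of at least 5 CPM in the higher group and, except for the interaction, no overlap between the groups. From these, mainly genes are given whose call held with any 1 library left out. The groups, the comparisons, the tests, the lists, the naming rule and the alternatives were fixed before the data were examined, except where an alternative or a test is said to be chosen afterwards.

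The fit was tested on simulated data with 260 changed genes among 10607 for knockdown against control at ZT8. It made 157 calls, of which 13 were of unchanged genes and 0 had the wrong sign. It found 16% of genes changed 1.25-fold, 62% of those changed 1.5-fold, 96% of those changed 2-fold and 100% of those changed 4-fold, so small changes were often missed. With no simulated change at ZT16 it made 0 calls. Camera called 2 of 2 shifted lists and 0 of the other 8, limma-voom made 160 calls with 14 false, and DESeq2 1.42.0 made 163 with 17 false. The simulated lists held random genes drawn independently of each other. They could not show how often camera makes false calls on lists whose genes move together. In the real data the estimated correlation was, for example, 0.68 for oxidative phosphorylation at ZT8. The F test of diffSplice found 55% of the switched genes.

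The alternatives were other scaling factors (RLE, upper quartile), no filter or a stricter one, DESeq2, limma-voom, limma-trend on log2 of TPM plus 1 or plus 0.1, only the 6 libraries of a contrast, replicate numbers as an additive term, a fit to transcripts, and each library left out in turn. Fits without rRNA genes, without 2 libraries that stood apart, and the Simes test on the real data were chosen after the data were seen. Nothing in the labels says that replicate numbers mark a shared batch. At ZT8 the numbers in the library names differ from those in the titles, except for knockdown ZT8 replicate 1. At ZT16 they match. Residuals of libraries with the same number were correlated above 0.1 in 6 of 18 pairs (range -0.170 to 0.273), and in all 3 pairs only between knockdown ZT8 and knockdown ZT16. With the replicate number as a block the count of genes changed with time in knockdown was 2280 against 2488. Library names of the ZT8 and ZT16 sets differ in style, so a batch and the time of collection cannot be told apart. Group comparisons of 3 against 3 libraries have a smallest exact permutation p of 0.1, so no permutation p is given for them. Counts of genes and lists were set against other splits of the libraries. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.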

Results

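Messenger RNA of fly heads was measured in 12 libraries, 3 each of control at ZT8, knockdown at ZT8, control at ZT16 and knockdown at ZT16. Total expected counts per library were 36885481 to 37676778 at ZT8 and 25844821 to 31848667 at ZT16. rRNA took 2.92% to 5.89% of the counts in control ZT8, 2.58% to 7.09% in knockdown ZT8, 6.40% to 8.05% in control ZT16 and 8.94% to 9.73% in knockdown ZT16. Group changes at ZT16 and with time are therefore open to differences in RNA preparation. The 10 most abundant genes took 12.1% to 14.99%. After filtering, 10717 genes were tested. The first principal component held 36.1% of the variance and placed the 6 control libraries below 0 (-43.5 to -10.2) and the 6 knockdown libraries above it (7.16 to 31.4). The second held 22.1% and placed the ZT8 libraries above 0 (10.3 to 24.6) and the ZT16 libraries below it (-46.3 to -5.89). Control ZT16 replicate 1 had the lowest value on both. In every comparison n = 3 libraries per group, and values in parentheses after a gene are log2 fold changes ± standard error, with coordinates on dm6.

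The knockdown targeted CG5808 (chromosome 3R, 24814903 to 24817007), which encodes dPPIL4, a cyclophilin-type peptidyl-prolyl isomerase. At ZT8 its level was 4.91, 4.81 and 4.93 CPM in the control libraries and 4.34, 2.91 and 4.49 CPM in the knockdown libraries, from 105 to 197 reads per library. At ZT16 it was 6.17, 5.86 and 5.16 CPM in control and 4.46, 4.08 and 3.71 CPM in knockdown, from 108 to 182 reads. All 3 knockdown libraries lay below all 3 control libraries at each time. The change did not pass the test at ZT8 (log2 fold change -0.32 ± 0.15, adjusted p = 0.188) and passed it at ZT16 (log2 fold change -0.49 ± 0.16, adjusted p = 0.0427) and over both times (log2 fold change -0.40 ± 0.11, adjusted p = 0.0168). At ZT16 the call ended without control ZT8 replicate 2 (0.0592) or 3 (0.0590), knockdown ZT8 replicate 1 (0.0516), control ZT16 replicate 1 (0.110) or 2 (0.0883), or knockdown ZT16 replicate 1 (0.0723), 2 (0.112) or 3 (0.139), with the adjusted p in parentheses. Its adjusted p was 0.0569 with no filter, 0.0522 with the replicate block and just over 0.05 with limma-voom and on TPM plus 0.1, and over all alternatives it ran from 0.0140 to 0.139. The gene overlaps CG34150 and asRNA:CR46096, reads of the hairpin could not be told from those of the gene, and whole heads hold many cells without the driver.

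At ZT8, in the light phase, the knockdown was compared with control to see which genes differed when per and tim transcripts were low. The clock gene per fell in knockdown heads (chromosome X, 2685580 to 2692780; 121 ± 4.42 against 145 ± 6.51 CPM; log2 fold change -0.26 ± 0.046, adjusted p = 0.00386), and all 3 knockdown libraries lay below all 3 control libraries. The span of per overlaps dyw, so with the strand setting not given its counts can hold reads of dyw. The partner gene of per, tim, also fell (659 ± 14.7 against 758 ± 16.6 CPM; log2 fold change -0.20 ± 0.051, adjusted p = 0.0202). This call ended without control ZT8 replicate 2 (0.103) or 3 (0.0695), or knockdown ZT8 replicate 2 (0.0561) or 3 (0.0541). It also ended in fits of the 6 ZT8 libraries alone (adjusted p = 0.0576) or with a block of replicate numbers within time (adjusted p = 0.0582). The other core clock genes did not pass the test: Clk was at -0.11 ± 0.091, cyc at -0.11 ± 0.067, vri at 0.11 ± 0.062, Pdp1 at -0.088 ± 0.069, cwo at 0.016 ± 0.050 and the blue-light receptor gene cry at 0.11 ± 0.083. Among clock regulators and outputs, Usp8 fell (-0.42 ± 0.044), as did the phosphatase subunit gene tws (-0.25 ± 0.043), while takeout (to), a clock output gene linked to feeding, rose (3.83 ± 0.24, 323 ± 112 against 22.8 ± 0.829 CPM). The clock neuron peptide gene Pdf fell (log2 fold change -0.47 ± 0.060, adjusted p = 4.59e-04).

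Many of the largest changes at ZT8 were in genes nearly silent in 1 genotype. Cyp12d1-d (chromosome 2R, 11123658 to 11125647), a cytochrome P450 gene, had 0 reads in control and 25.2 ± 5.77 CPM in knockdown, at least 981-fold higher, and CG18853 was at least 559-fold higher. The sum of Cyp12d1-d and the copy Cyp12d1-p differed far less, at 42.1 ± 10.4 CPM in knockdown and 4.67 ± 1.35 CPM in control. Rises were also called for lncRNA:CR45284 (7.30 ± 0.51), Hsc70-2 (5.84 ± 0.18), CG18095 (5.52 ± 0.93), Cyp309a2 (5.28 ± 0.39) and CG11854 (4.69 ± 0.43). The receptor gene mthl8 (chromosome 3L, 22428 to 26308) fell from 48.3 to 0.464 CPM (log2 fold change -6.69 ± 0.55, adjusted p = 4.85e-04). The antisense RNAs asRNA:CR45822 (-5.69 ± 0.29) and asRNA:CR45835 (-4.48 ± 0.25) fell, as did CG6654 (-1.93 ± 0.086) and the 4 neighbours on chromosome 2L Cks30A (-2.54 ± 0.44), lncRNA:CR45456 (-2.48 ± 0.30), CG17005 (-2.20 ± 0.27) and lncRNA:CR45457 (-2.18 ± 0.27). Among these 15 genes, Cyp12d1-p not counted, the adjusted p was at most 0.00477.

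Energy metabolism genes rose together at ZT8. In the oxidative phosphorylation list, of 68 members 60 rose and 0 fell over all genes tested (66 and 1 adjusted over the list alone) (median log2 fold change 0.35, adjusted p = 8.36e-24, and 0.469 with an estimated correlation). Examples were the electron transport subunit genes Cyt-c1 (0.37 ± 0.052), ND-24 (0.37 ± 0.053), SdhB (0.53 ± 0.080) and RFeSP (0.48 ± 0.072). In the glycolysis list, of 13 members 4 rose and 0 fell over all genes tested (8 and 0 adjusted over the list alone), among them lactate dehydrogenase Ldh (0.76 ± 0.11) and glycerol-3-phosphate dehydrogenase Gpdh1 (0.87 ± 0.16). The glycolysis list had median log2 fold change 0.26, adjusted p = 8.99e-04, and 0.555 with an estimated correlation, and its median was 0.44 without control ZT8 replicate 1. Muscle genes behaved alike: of 20 members 14 rose and 1 fell over all genes tested (15 and 1 adjusted over the list alone), with median log2 fold change 0.56, adjusted p = 1.31e-08, and 0.453 with an estimated correlation. They included the myosin light chain and troponin genes Mlc1 (0.84 ± 0.12), Mlc2 (0.68 ± 0.11), up (0.68 ± 0.11) and wupA (0.58 ± 0.10). Fat body markers gave 6 rises and 0 falls among 17 members by both adjustments, over all genes and adjusted over the list alone, with fit (2.33 ± 0.43) and the nuclear receptor gene Hnf4 (0.32 ± 0.052) as examples (median log2 fold change 0.33, adjusted p = 9.36e-06, and 0.429 with an estimated correlation). That median was 0.59 without control ZT8 replicate 1. Male-biased head genes had 2 rises and 0 falls among 9 members by both adjustments (median log2 fold change 0.17, adjusted p = 0.00437, and 0.555 with an estimated correlation), and the median was 0.33 and 0.081 without control ZT8 replicates 1 and 2. Female-biased head genes had a higher median, with 4 rises and 0 falls among 6 members by both adjustments (median log2 fold change 1.08, adjusted p = 0.0314, and 0.555 with an estimated correlation). This call ended without knockdown ZT8 replicate 3 (0.0772) or control ZT16 replicate 1 (0.0549).

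Detoxification genes rose more often than they fell at ZT8: of 52 members 19 rose and 5 fell over all genes tested (23 and 7 adjusted over the list alone) (median log2 fold change 0.29, adjusted p = 1.16e-13, and 0.429 with an estimated correlation). Cyp6a2 (2.04 ± 0.074, 88.8 ± 3.01 against 21.5 ± 1.64 CPM), Cyp6w1 (1.95 ± 0.10) and the glutathione transferase gene GstE1 (1.61 ± 0.078) rose, and Cyp28a5 fell (-0.86 ± 0.064). Photoreceptor genes went the other way: of 14 members 0 rose and 6 fell over all genes tested (0 and 7 adjusted over the list alone) (median log2 fold change -0.18, adjusted p = 2.40e-04, and 0.429 with an estimated correlation). Falls were called for the opsin genes Rh5 (-0.67 ± 0.055), Rh6 (-0.44 ± 0.063) and Rh3 (-0.39 ± 0.049) and the eye transcription factor gene glass, gl (-0.19 ± 0.039). The eye pigment transporter gene w, carried as a marker on many transgenes, rose (1.05 ± 0.10). Antennal markers rose in 10 and fell in 1 of 20 members (11 and 1 adjusted over the list alone; median log2 fold change 0.49, adjusted p = 0.00115, and 0.555 with an estimated correlation). The median stayed at 0.49 with a5 and Obp59a, which had 0 reads in control, set to their bounds, but was 0.18 on TPM and 0.31 on TPM less the median of all genes. Obp83a lay between 0.175 and 0.401 CPM in the 3 control ZT8 libraries and control ZT16 replicate 1, and between 2.01 and 9.14 CPM in the other 8 libraries.

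Some immune and stress genes also changed at ZT8. The Bomanin genes BomBc1 (2.49 ± 0.25) and BomS4 (1.32 ± 0.11), the thioester protein gene Tep4 (2.33 ± 0.12) and the recognition protein gene GNBP1 (0.55 ± 0.062) rose, while PGRP-SD fell (-1.63 ± 0.30). The stress gene TotM rose (3.20 ± 0.58), with 145, 149.8 and 33.0 CPM in the knockdown libraries against 10.6 to 13.5 CPM in control. Hsp23 rose (0.61 ± 0.13) and the activity-regulated gene Arc1 fell (-0.51 ± 0.093). As groups, heat shock genes (2 rises and 0 falls over all genes, 2 and 0 adjusted over the list alone; adjusted p = 0.136), Turandot genes (4 and 0, and 6 and 1 alone; adjusted p = 0.114) and antimicrobial peptide genes (6 and 0, and 7 and 1 alone; adjusted p = 0.192) were not called by camera, while fry called the Turandot genes up (adjusted p = 0.0411). The antimicrobial list had a median of -0.16 and a mean of -0.28, against an upward direction of the test. Of 27 immune recognition and signalling genes 7 rose and 3 fell (12 and 5 adjusted over the list alone), with median log2 fold change 0.15, adjusted p = 0.0394, and 0.555 with an estimated correlation. This call ended without control ZT8 replicate 2 (0.108) or 3 (0.110), knockdown ZT8 replicate 3 (0.729), control ZT16 replicate 1 (0.0619), or knockdown ZT16 replicate 1 (0.0735), 2 (0.0550) or 3 (0.0695).

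In all, 1671 genes changed at ZT8 by edgeR, 947 up and 724 down, and 285 changed at least 2-fold. The count was 2735 without control ZT8 replicate 1, 673 without replicate 2 and 733 without replicate 3. It was 920 without knockdown ZT8 replicate 1 and 1004 without replicate 2. It was 871 from the 6 ZT8 libraries alone, 1088 genes by a fit to transcripts and 2137 without control ZT16 replicate 1 and knockdown ZT8 replicate 3. Of 34 lists, 14 were called, of which 8 held with any 1 library left out; 0 of the 14 held with an estimated correlation and fry called 13. On TPM the median of all genes lay at -0.13 and 553 genes rose and 1813 fell, so the balance of rises and falls depended on the scaling.

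**Figure D1:**
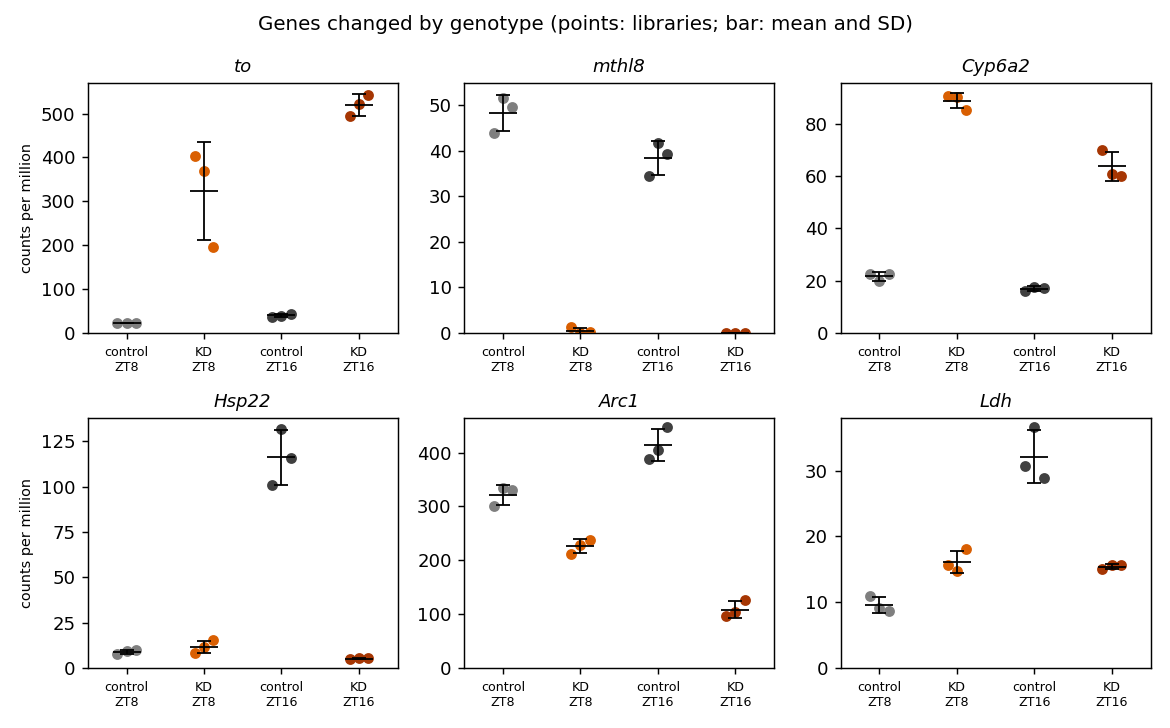
CPM (vertical axes, from 0) of 6 genes that changed with genotype, in 4 groups of genotype and time; points are libraries, bars the mean and SD of 3. to and Cyp6a2 lay above control at both times and mthl8 near 0 in knockdown; Hsp22 reached 116 CPM in control at ZT16 alone.

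At ZT16, in the dark phase, the same comparison was made when per and tim transcripts were high. The gene per fell again (234 ± 6.17 against 299 ± 8.71 CPM; log2 fold change -0.35 ± 0.046, adjusted p = 4.22e-04), with the 3 knockdown libraries below the 3 control libraries, whereas tim was at -0.078 ± 0.051 and did not pass the test (adjusted p = 0.291). Clk, whose protein activates per and tim, had 8.76 ± 0.727 against 10.9 ± 1.42 CPM and overlapped between the groups; its call was log2 fold change -0.31 ± 0.10, adjusted p = 0.0437. That call ended without control ZT8 replicate 2 (0.0657) or 3 (0.0649), knockdown ZT8 replicate 1 (0.0594) or 2 (0.0566), control ZT16 replicate 2 (0.167) or 3 (0.115), or knockdown ZT16 replicate 1 (0.177), 2 (0.106) or 3 (0.0553). The genes vri (-0.17 ± 0.062, adjusted p = 0.0726), cwo (0.14 ± 0.050, adjusted p = 0.0636), cry (0.14 ± 0.085), cyc (-0.082 ± 0.068) and Pdp1 (-0.048 ± 0.069) did not pass. Usp8 fell (-0.40 ± 0.045), to rose (3.70 ± 0.24, 519 ± 24.6 against 39.8 ± 3.37 CPM), the kinase gene bsk rose (0.35 ± 0.054) and the insulin-like peptide gene Ilp3 rose (1.77 ± 0.38).

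Genes silent in 1 genotype showed the same pattern at ZT16. Cyp12d1-d was at least 654-fold and CG18853 at least 380-fold higher in knockdown, and mthl8, with 0 reads in knockdown and 38.5 CPM in control, was at least 1050-fold lower. Rises were called for Hsc70-2 (4.74 ± 0.17), CG11854 (4.47 ± 0.43), Ccp84Ag (4.27 ± 0.44) and Cyp309a2 (4.14 ± 0.38), and asRNA:CR45822 fell (-7.66 ± 0.36). The other 6 of the 8 largest falls were of genes highest in control ZT16 replicate 1. One was Jon99Cii, a digestive protease gene, with 233, 4.43 and 0.376 CPM in the 3 control libraries and 2 reads in all of knockdown, a ratio of 3.07e-04 (95% counting interval 3.72e-05 to 0.00111). Its call (adjusted p = 0.0344) ended without control ZT8 replicate 3 (0.0688), knockdown ZT8 replicate 1 (0.0692), or knockdown ZT16 replicate 1 (0.104), 2 (0.0993) or 3 (0.102). The calls of the other 5 ended without 4 to 10 of the libraries, and they are not described. Control ZT16 replicate 1 also had 2295 CPM of midgut enzyme transcripts and 922 CPM of ovary and eggshell transcripts, against medians of 1.41 and 2.22 CPM in the other 11.

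Among the named genes, Hsp22, Arc1 and Ldh fell at ZT16. Hsp22, a mitochondrial small heat shock protein gene (chromosome 3L, 9372931 to 9374964), fell (5.16 ± 0.227 against 116 ± 15.2 CPM; log2 fold change -4.49 ± 0.22, adjusted p = 1.11e-06). Arc1, which encodes a capsid-forming protein induced by neuronal activity (chromosome 2R, 14357927 to 14360297), fell (log2 fold change -1.93 ± 0.097, adjusted p = 4.35e-07), as did its neighbour Arc2 (-0.80 ± 0.12). Their groups moved little: heat shock genes were not called by camera or fry (3 rises and 2 falls over all genes, 4 and 5 adjusted over the list alone; adjusted p = 0.259), and of 13 activity-regulated genes 0 rose and 4 fell by both adjustments (median log2 fold change -0.10, adjusted p = 0.00656, and 0.575 with an estimated correlation). The activity call ended without control ZT8 replicate 1 (0.134), 2 (0.0584) or 3 (0.0648), or knockdown ZT16 replicate 1 (0.0564) or 2 (0.0521), and its median was -0.044 without control ZT16 replicate 2 and -0.066 without knockdown ZT16 replicate 1. Ldh fell (15.4 ± 0.357 against 32.1 ± 4.02 CPM; log2 fold change -1.06 ± 0.11, adjusted p = 9.05e-05) while other glycolysis genes rose. In the list of 13 members 7 rose and 1 fell over all genes tested (11 and 1 adjusted over the list alone) (median log2 fold change 0.28, adjusted p = 0.00341, and 0.600 with an estimated correlation), with Gapdh1 (0.59 ± 0.12), Gapdh2 (0.30 ± 0.063) and Gpdh1 (0.74 ± 0.16) up. In the oxidative phosphorylation list, of 68 members 46 rose and 0 fell over all genes tested (58 and 0 adjusted over the list alone) (median log2 fold change 0.27, adjusted p = 1.53e-14, and 0.575 with an estimated correlation). Rises included ND-13B (0.47 ± 0.073), ATPsynbeta (0.38 ± 0.070), Cyt-c1 (0.28 ± 0.052) and ND-SGDH (0.23 ± 0.043).

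Neuron and glia markers rose at ZT16. Of 24 neuron markers, 13 rose and 0 fell by both adjustments, over all genes tested and adjusted over the list alone (median log2 fold change 0.21, adjusted p = 3.03e-06, and 0.575 with an estimated correlation). Among them were the transmitter transporter genes VGAT (0.47 ± 0.065) and VGlut (0.34 ± 0.058) and the vesicle fusion genes Snap25 (0.38 ± 0.066) and comt (0.37 ± 0.066). Among glia markers, of 21 members 7 rose and 2 fell over all genes tested (10 and 3 adjusted over the list alone) (median log2 fold change 0.14, adjusted p = 0.00197, and 0.575 with an estimated correlation). Examples were Obp44a (1.28 ± 0.079), Gat (0.53 ± 0.098), nrv2 (0.43 ± 0.066) and Mdr65 (0.38 ± 0.062). Muscle markers rose less uniformly: of 20 members 9 rose and 0 fell over all genes tested (11 and 2 adjusted over the list alone), with Mlc1 (0.64 ± 0.12), Tm1 (0.42 ± 0.085) and up (0.52 ± 0.11). The median was 0.37, the mean -0.15 had the other sign, and the camera test gave a rise (adjusted p = 4.65e-04; adjusted p = 0.575 with an estimated correlation). Control ZT16 replicate 1, which held gut and ovary transcripts, had a geometric mean of 191 CPM over the list, against 129 and 111 CPM in the other 2 controls and 121 to 148 CPM in knockdown. Detoxification genes were mixed, as 12 rose and 8 fell (15 and 10 adjusted over the list alone) (median log2 fold change 0.077, adjusted p = 8.09e-04, and 0.575 with an estimated correlation), and the median was 0.038 without control ZT16 replicate 2 and 0.059 on TPM (0.12 less the median of all genes). Cyp6a2 (1.91 ± 0.075, 63.6 ± 5.46 against 16.9 ± 0.790 CPM), GstE1 (1.51 ± 0.082) and Cyp6w1 (1.33 ± 0.10) rose and Cyp28a5 fell (-0.84 ± 0.064).

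Protein synthesis and degradation genes fell at ZT16 by small amounts. Among 84 ribosomal protein genes, 0 rose and 21 fell (0 and 23 adjusted over the list alone) (median log2 fold change -0.12, adjusted p = 1.08e-05, and 0.702 with an estimated correlation), and 82 of 84 were lower; RpS21 was an example (-0.26 ± 0.053). Among 32 proteasome genes, 0 rose and 12 fell (0 and 17 adjusted over the list alone) (median log2 fold change -0.17, adjusted p = 8.58e-05, and 0.620 with an estimated correlation), and all 32 were lower, with Prosalpha3 (-0.35 ± 0.060), Prosbeta3 (-0.31 ± 0.069) and Rpn9 (-0.26 ± 0.056). The opsin genes Rh5 (-0.64 ± 0.055), Rh3 (-0.37 ± 0.049) and Rh6 (-0.37 ± 0.063) fell again, as did gl (-0.25 ± 0.040). In the photoreceptor list of 14 members 0 rose and 7 fell over all genes tested (1 and 7 adjusted over the list alone) (median log2 fold change -0.19, adjusted p = 0.00686, and 0.575 with an estimated correlation). That call ended without control ZT16 replicate 2 (0.0555). Single genes that fell were the translation kinase gene PEK (-0.46 ± 0.056), the immune factor gene Rel (-0.50 ± 0.071) and the antioxidant factor gene cnc (-0.31 ± 0.047). The lists that hold them were not called by camera or fry, with these values by camera: endoplasmic reticulum stress (adjusted p = 0.259), immune recognition and signalling (adjusted p = 0.373) and antioxidant defence (adjusted p = 0.728). BomS4 (1.49 ± 0.11) and Tep4 (1.66 ± 0.12) rose and w rose (1.39 ± 0.10). In all, 2379 genes changed at ZT16, 1204 up and 1175 down, and 347 changed at least 2-fold. The count was 1309, 1537 and 1447 without knockdown ZT16 replicates 1, 2 and 3, 1303 genes by a fit to transcripts and 2063 without control ZT16 replicate 1 and knockdown ZT8 replicate 3; with upper-quartile factors 944 rose and 1477 fell, and on TPM 602 rose and 1062 fell. Of 34 lists 14 were called, 8 of them with any 1 library left out; 0 held with an estimated correlation and fry called 19.

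The 2 times were then compared for the genes they shared. At both times 383 genes rose, against 106 if the sets were independent, and 287 fell, against 79.4, while 46 changed in opposite directions. Across all genes the fold changes at ZT8 and ZT16, which share no library, had a Pearson r of 0.48 and a Spearman rho of 0.41. The overlap of 670 genes was 1036, 373 and 391 without control ZT8 replicates 1, 2 and 3, 427 without knockdown ZT8 replicate 1, and 415 with each comparison fitted on its own libraries. Averaged over both times, per fell (log2 fold change -0.31 ± 0.033, adjusted p = 5.76e-05). So did tim (log2 fold change -0.14 ± 0.036, adjusted p = 0.0133), a call that ended without control ZT16 replicate 3 (0.0515). In this average 1574 genes rose and 1510 fell (1308 and 1976 with upper-quartile factors, 831 and 2748 on TPM). The total was 3274 without control ZT16 replicate 1 and knockdown ZT8 replicate 3, and 8 lists were called, 6 of them with any 1 library left out. In the oxidative phosphorylation list, of 68 members 66 rose and 1 fell over all genes tested (66 and 1 adjusted over the list alone) (median log2 fold change 0.30, adjusted p = 5.11e-24, and 0.487 with an estimated correlation). Of 20 muscle genes 15 rose and 1 fell over all genes tested (median log2 fold change 0.43, adjusted p = 2.09e-07, and 0.487 with an estimated correlation). Of 52 detoxification genes 20 rose and 8 fell (median log2 fold change 0.20, adjusted p = 1.61e-09, and 0.471 with an estimated correlation). Among 17 fat body markers 7 rose and 0 fell (median log2 fold change 0.25, adjusted p = 1.29e-04, and 0.471 with an estimated correlation). Among 14 photoreceptor markers 1 rose and 8 fell (median log2 fold change -0.16, adjusted p = 3.46e-04, and 0.471 with an estimated correlation). With fry 15 lists were called. Lists tied to RNA processing were not called by camera: of 45 spliceosome genes 2 rose and 11 fell (adjusted p = 0.246), and of 15 cyclophilin genes 0 rose and 4 fell (adjusted p = 0.238). By fry the cyclophilin genes fell (adjusted p = 0.00910), as did RNA polymerase II and elongation factors (adjusted p = 0.0157; 0.201 by camera), of which 1 rose and 8 fell among 37.

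In control heads the change from ZT8 to ZT16 shows the daily course against which the knockdown was set, although the sets of the 2 times can also differ by batch. Clock genes moved in opposite phases: per rose (log2 fold change 1.04 ± 0.047, adjusted p = 1.56e-07) with tim (1.15 ± 0.052), vri (0.63 ± 0.062) and Pdp1 (0.75 ± 0.069). Clk fell (-1.92 ± 0.097) with cry (-1.99 ± 0.087, 62.0 ± 2.84 against 246 ± 34.1 CPM). cyc (0.023 ± 0.067), cwo (0.075 ± 0.050) and CG5808 (0.23 ± 0.15) did not pass. Output and regulator genes Usp8 (-0.67 ± 0.044), nmo (-0.38 ± 0.051) and Ugt35B1 (-1.40 ± 0.075) fell. Among the other named genes, Achl (5.33 ± 0.22, 193 ± 8.67 against 4.78 ± 0.373 CPM), Hsp22 (3.72 ± 0.20) and Ldh (1.75 ± 0.11) rose. Jhe, a juvenile hormone esterase gene, fell (-4.15 ± 0.27), and the neighbours Cks30A (-1.94 ± 0.43), lncRNA:CR45456 (-2.07 ± 0.29), CG17005 (-1.99 ± 0.27) and lncRNA:CR45457 (-2.21 ± 0.27), which were also lower in knockdown at ZT8, fell.

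Neuronal genes were lower at ZT16 in control. Among 24 neuron markers, 0 rose and 16 fell (0 and 17 adjusted over the list alone) (median log2 fold change -0.25, adjusted p = 1.62e-07, and 0.945 with an estimated correlation). Falls included the channel genes para (-0.59 ± 0.056) and cac (-0.37 ± 0.063), fne (-0.43 ± 0.076) and the active zone gene brp (-0.33 ± 0.054). Of 28 neuropeptide genes 0 rose and 10 fell by both adjustments, over all genes and adjusted over the list alone (median log2 fold change -0.29, adjusted p = 7.80e-04, and 0.945 with an estimated correlation), with Capa (-0.50 ± 0.073), Trissin (-0.43 ± 0.077), AstC (-0.38 ± 0.060) and Nplp1 (-0.31 ± 0.068). Activity-regulated genes fell, with 1 rise and 6 falls among 13 by both adjustments, over all genes and adjusted over the list alone (median log2 fold change -0.20, adjusted p = 0.00272, and 0.945 with an estimated correlation), led by Hr38 (-1.28 ± 0.17). Muscle genes rose, as 9 rose and 1 fell (11 and 1 adjusted over the list alone) (median log2 fold change 0.40, adjusted p = 7.80e-04, and 0.945 with an estimated correlation). Proteasome genes did as well, and 9 rose and 0 fell (13 and 0 adjusted over the list alone) (median log2 fold change 0.16, adjusted p = 8.21e-04, and 0.945 with an estimated correlation). Of 68 oxidative phosphorylation genes 15 rose and 1 fell by both adjustments, the second adjusted over the list alone (median log2 fold change 0.14, adjusted p = 7.80e-04, and 0.945 with an estimated correlation), and the median was 0.22 and 0.085 without control ZT8 replicates 1 and 2. Cyt-c-p (0.82 ± 0.076), Mlc1 (0.68 ± 0.12) and Rpn8 (0.34 ± 0.058) were examples. In all 1281 genes rose and 1261 fell, but 504 rose and 2297 fell on TPM, where the median of all genes lay at -0.11, and 1145 rose and 1320 fell with upper-quartile factors. The total of 2542 was 1532 without control ZT8 replicate 2 and 1689 without replicate 3, and 2289 without control ZT16 replicate 1 and knockdown ZT8 replicate 3. The 4 genes with the largest rises were highest in control ZT16 replicate 1, their calls ended without 4 to 10 of the libraries, and they are not described. Of 34 lists 7 were called, 6 of them with any 1 library left out; 0 held with an estimated correlation and fry called 6.

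In knockdown heads the same clock genes moved with time. per rose (log2 fold change 0.95 ± 0.047, adjusted p = 2.52e-07) with tim (1.28 ± 0.052), Pdp1 (0.79 ± 0.069) and vri (0.35 ± 0.062), and Clk (-2.13 ± 0.099) and cry (-1.95 ± 0.087) fell. cwo rose (log2 fold change 0.20 ± 0.050, adjusted p = 0.0139), a call that ended without knockdown ZT8 replicate 1 (0.0580) or knockdown ZT16 replicate 2 (0.0666), and CG5808 was at 0.060 ± 0.16. Among 13 activity-regulated genes, 0 rose and 11 fell (0 and 12 adjusted over the list alone) (median log2 fold change -0.39, adjusted p = 2.79e-10, and 0.204 with an estimated correlation). Among 84 ribosomal protein genes 0 rose and 40 fell (2 and 44 adjusted over the list alone) (median log2 fold change -0.17, adjusted p = 1.56e-10, and 0.926 with an estimated correlation). Glia markers rose, as 9 rose and 1 fell (10 and 1 adjusted over the list alone) of 21 (median log2 fold change 0.33, adjusted p = 3.99e-06, and 0.363 with an estimated correlation). Detoxification genes fell, as 4 rose and 20 fell (4 and 23 adjusted over the list alone) of 52 (median log2 fold change -0.37, adjusted p = 5.87e-05, and 0.839 with an estimated correlation). Heat shock genes fell too, and 1 rose and 9 fell by both adjustments, the second adjusted over the list alone (median log2 fold change -0.57, adjusted p = 0.00300, and 0.518 with an estimated correlation). The heat shock median was -0.34 without knockdown ZT8 replicate 3 and -0.37 without knockdown ZT16 replicate 2, and -0.42 on TPM (-0.36 less the median of all genes). Among 27 immune recognition and signalling genes 0 rose and 12 fell (0 and 12 adjusted over the list alone), with median log2 fold change -0.22, adjusted p = 0.00108, and 0.518 with an estimated correlation. Among 11 Turandot and JAK/STAT target genes 0 rose and 4 fell (0 and 5 adjusted over the list alone), with median log2 fold change -0.50, adjusted p = 0.0179, and 0.363 with an estimated correlation. That median was -0.91 without knockdown ZT16 replicate 2. Of 34 lists 9 were called, 7 of them with any 1 library left out, and fry called 10. In all 1268 genes rose and 1220 fell, but 650 rose and 1268 fell on TPM, and 1072 rose and 1344 fell with upper-quartile factors. The total of 2488 was 1572 without knockdown ZT16 replicate 1 and 2280 with the replicate number as a block, and 2536 without control ZT16 replicate 1 and knockdown ZT8 replicate 3. Between genotypes, 583 genes rose with time in both, against 152 if independent, and 520 fell in both, against 144.

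**Figure D2:**
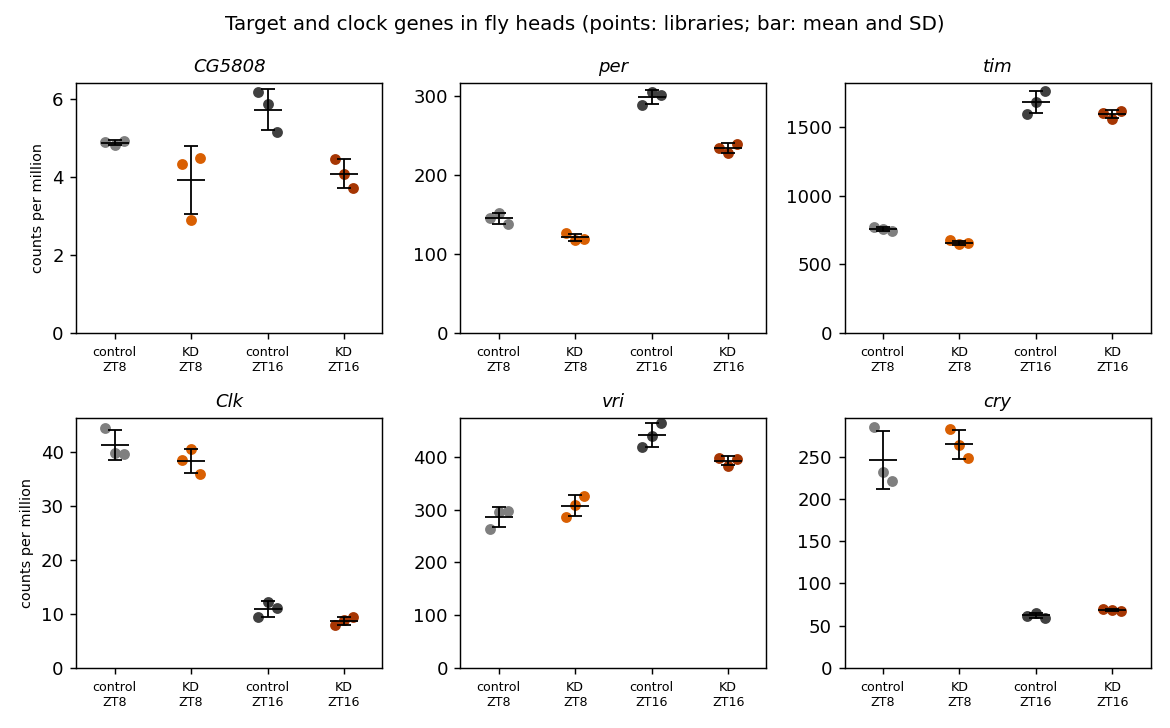
CPM (vertical axes, from 0) of CG5808 and 5 clock genes in control and knockdown heads at ZT8 and ZT16; points are libraries, bars the mean and SD of 3. per was lower in knockdown at both times (121 against 145 CPM and 234 against 299 CPM) and higher at ZT16 than at ZT8 in both genotypes.

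Whether the knockdown effect differed between the times was tested by the interaction. No core clock gene passed: per was at -0.090 ± 0.065 (adjusted p = 0.451), tim at 0.12 ± 0.072 (adjusted p = 0.342), Clk at -0.21 ± 0.14, vri at -0.27 ± 0.088 and CG5808 at -0.17 ± 0.22 (adjusted p = 0.697). A difference between genotypes in the fold change of per or tim from ZT8 to ZT16 was thus not detected with edgeR. The test is on the log2 scale, and samples at ZT8 and ZT16 alone do not measure a daily range. Hsp22 (log2 fold change -4.89 ± 0.29, adjusted p = 9.08e-05), Ldh (log2 fold change -1.81 ± 0.15, adjusted p = 4.19e-04) and Arc1 (log2 fold change -1.42 ± 0.13, adjusted p = 8.71e-04) had a lower knockdown effect at ZT16 and the eye surface gene retinin a higher one (log2 fold change 0.96 ± 0.13, adjusted p = 0.00747). These 4 were the named genes, of 47 called, whose call held with any 1 library left out. In all 448 genes differed, 286 of them with a higher effect at ZT16, and 531 differed without control ZT16 replicate 1 and knockdown ZT8 replicate 3. The count was 1107, 22 and 27 without control ZT8 replicates 1, 2 and 3, 116 and 257 without knockdown ZT8 replicates 1 and 2, 269 and 24 without control ZT16 replicates 2 and 3, and 19, 292 and 73 without knockdown ZT16 replicates 1, 2 and 3, so it was not stable.

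Because the table was per transcript, the shares of the transcripts of the clock genes were compared; 6 of the 8 clock genes could be tested among 5448 genes. At ZT16 tim passed the diffSplice F test of limma (adjusted p = 0.0304). Its variant R made 3.84% ± 0.405 (SD) of tim transcripts in control and 2.46% ± 0.361 in knockdown, and variant S, the most abundant, 31.7% ± 1.13 and 30.7% ± 0.539. Over both times tim also passed (adjusted p = 0.0180), a test not repeated with libraries left out. Looked up afterwards, variant M made 15.3% ± 1.00 of tim transcripts in control and 19.995% ± 2.36 in knockdown at ZT8, and 11.6% ± 0.458 and 13.3% ± 0.687 at ZT16. Its own adjusted p in limma was 0.0106 at ZT8, 0.242 at ZT16 and 0.00280 over both times, and that of variant R was 0.906, 0.00212 and 0.0525. The call ended without control ZT8 replicate 2 or any 1 of the 6 ZT16 libraries, with the replicate block and with the replicate block within time, where the number of clock genes called was 0. At ZT8 0 clock genes passed, while 662 of all genes did and 1438 had an unadjusted p under 0.05. There tim had an adjusted p = 0.161, and 1 clock gene was called without control ZT8 replicate 1, with the replicate block within time or with the Simes test. With time, Pdp1, tim, vri and per changed usage in both genotypes (adjusted p at most 0.0488) and Clk in control (adjusted p = 0.0453; 0.0796 in knockdown). Variants T and B of tim had identical counts, and RSEM estimates how reads are divided between transcripts, so such shares are uncertain.

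**Figure D3:**
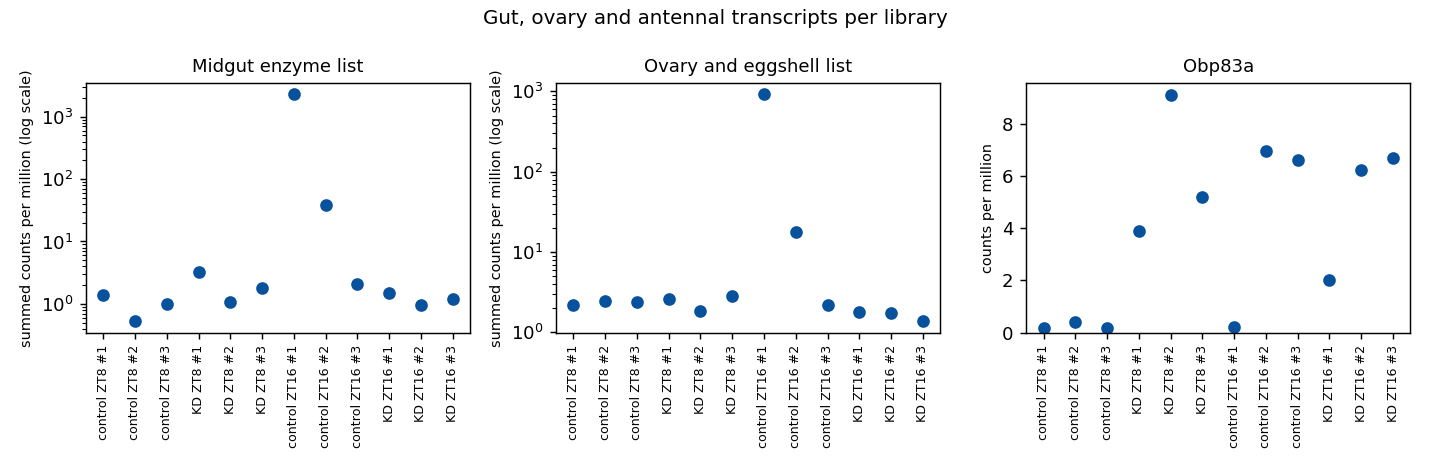
Summed CPM of midgut enzyme genes and of ovary and eggshell genes (log axes), and CPM of Obp83a (axis from 0), in each of the 12 libraries (points). Control ZT16 replicate 1 stood at 2295 and 922 CPM; Obp83a was at most 0.401 CPM in it and in the 3 control ZT8 libraries.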

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

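These genes and lists were singled out because the knockdown effect differed between ZT8 and ZT16 by the interaction test. Chosen only after the result was seen were the tests of the gut and ovary transcripts, of knockdown and time for the antennal transcripts, and of shared reads and of the knockdown itself for genes silent in 1 genotype. Values in parentheses are the effect at ZT16 minus that at ZT8.

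Several stress genes had a lower effect at ZT16. Hsp22 differed by -4.89 (ZT8 0.40, ZT16 -4.49) and TotM by -4.21 (ZT8 3.20, ZT16 -1.01), along with TotC (-2.71) and Hsc70-2 (-1.11). Outside the stress lists CG7910 (-3.11) and CG5966 (-2.20) also had a lower effect. Ldh, which makes lactate from pyruvate, went from a rise to a fall, -1.81 (ZT8 0.76, ZT16 -1.06), and Arc1 fell more, -1.42 (ZT8 -0.51, ZT16 -1.93). Defence genes with a lower effect were GstD2 (-1.49), CG33470 (-0.97), Prx2540-1 (-0.72), Tep4 (-0.67), Cyp6w1 (-0.62), GstE6 (-0.44), GstD1 (-0.40), Ugt36E1 (-0.37) and dl (-0.41). So were the regulators PEK (-0.37), cnc (-0.32) and Xrp1 (-0.40), the repair and splicing genes DNApol-zeta (-0.56) and SmE (-0.46), the proteasome genes Prosbeta3 (-0.44), Prosbeta2 (-0.36) and Prosalpha3 (-0.34) and the ribosomal genes RpL22 (-0.35), RpS16 (-0.31), RpS25 (-0.30) and RpL17 (-0.23).

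Synaptic genes had a higher effect at ZT16: Snap25 (0.57), Syt1 (0.49), Syx1A (0.42), brp (0.37), para (0.36) and DAT (0.45). So did the clock neuron peptide gene Pdf, 0.44 (ZT8 -0.47, ZT16 -0.029), the light signalling gene Galphaq (0.36), and the transport genes nrv2 (0.49), Mdr65 (0.54) and Gat (0.55). Others were Act57B (0.65), skl (0.83), retinin (0.96), CG40298 (1.08), bgm (1.14), CG17264 (1.16) and CG13026 (1.36). Of these 47 genes, 45, 4 and 5 were called without control ZT8 replicates 1, 2 and 3, and 15, 28 and 33 without knockdown ZT8 replicates 1, 2 and 3. The numbers were 31, 28 and 5 for control ZT16 and 4, 25 and 8 for knockdown ZT16. Of 100 splits of the 12 libraries 1, the real one, gave as many as the 448 genes. The highest other gave 394 with the real groups kept at ZT16, and the real count was 19 without knockdown ZT16 replicate 1, 22 and 27 without control ZT8 replicates 2 and 3 and 24 without control ZT16 replicate 3. The splits thus say little for this count.

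Among lists, neuron markers (0.34), glia markers (0.13), the phototransduction and retinoid pathway (0.16) and hemocyte markers (0.28) had a higher median effect at ZT16. Ribosomal proteins (-0.19), the proteasome (-0.24), detoxification enzymes (-0.20), antioxidant defence (-0.13), activity-regulated genes (-0.26) and olfactory and antennal markers (-0.37) had a lower one. So did antimicrobial peptides and Bomanins (-0.80), immune recognition and signalling (-0.20), Turandot stress genes and JAK/STAT targets (-0.89) and heat shock proteins (-0.14). On TPM 7 medians were over 1.5 times smaller: antimicrobial -0.33 (-0.38 less the median of all genes), heat shock -0.030 (-0.080), antennal -0.16 (-0.21), ribosomal -0.11 (-0.16), activity-regulated -0.14 (-0.19), proteasome -0.15 (-0.20) and detoxification -0.13 (-0.18). Hemocyte was higher at 0.46 (0.41) and phototransduction at 0.26 (0.21). All 84 ribosomal and all 32 proteasome genes were lower, with 4 and 3 of them called (10 and 21 adjusted over the list alone). The hemocyte call ended without knockdown ZT8 replicate 2 (0.269). The antimicrobial call ended without knockdown ZT8 replicate 3 (0.352) or control ZT16 replicate 1 (0.0589). Its median was -0.19 without knockdown ZT8 replicate 3, and without both libraries the median was -0.084 and the direction of the test reversed. The heat shock call ended without control ZT8 replicate 2 (0.0671) or knockdown ZT8 replicate 3 (0.0708). Other medians that moved over 1.5 times were hemocyte (0.17 and 0.75 without knockdown ZT8 replicates 2 and 3), heat shock (-0.25, -0.21 and -0.091 without knockdown ZT8 replicates 1, 2 and 3), and Turandot (-0.55) and phototransduction (0.086) without knockdown ZT8 replicate 3. Without control ZT8 replicate 1 detoxification was at -0.38 and antioxidant defence at -0.24. Activity-regulated genes were at -0.17 without knockdown ZT8 replicate 2 and -0.16 without control ZT16 replicate 2, and antennal markers at -0.21 without control ZT16 replicate 3 or knockdown ZT16 replicate 1. With an estimated correlation the smallest adjusted p of the 14 was 0.225 and fry called 2. Chance was not excluded for the number of lists, since 14 of 100 splits gave 14 or more and the highest other gave 18. These medians are also open to the depth and batch of the ZT8 and ZT16 sets.

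The first pattern weighed was gut and ovary transcripts in control ZT16 replicate 1. Its midgut enzyme sum was 1629 times the median of the other 11 libraries, and 418 genes were over 5 times the highest of the others. A change with time or genotype was argued against, since control ZT16 replicate 3 held 0.0923% of the midgut sum of replicate 1. Replicate 2, with 39.1 CPM of midgut and 17.7 CPM of ovary transcripts, held 1.70% and 1.92% of replicate 1, a ratio of 1.13, so carry-over of replicate 1 may be a source. RNA of other body parts in the sample is a candidate explanation, and no biological explanation was tested beyond time and genotype.

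The second was the low level of some antennal transcripts in the 3 control ZT8 libraries and control ZT16 replicate 1. Os-C was 0 to 0.0678 CPM in these 4 and 0.724 to 5.56 CPM in the other 8. Orco (3.96 to 6.71 against 3.27 to 6.84) and Obp28a (6.45 to 9.67 against 5.30 to 9.91) overlapped. Snmp1 separated by genotype instead, at both times. It was 12.4 to 14.3 CPM in the control libraries and 19.5 to 22.5 CPM in the knockdown libraries. The span of Snmp1 overlaps SNF4Agamma, so with the strand setting not given its counts can hold reads of that gene. Missing antennae were argued against by the test set beforehand, since the odorant receptor sum of control ZT8 reached 126% of the median of the other 9 libraries. Looked up afterwards, Or63a and Or43b made 47.7% to 67.6% of that sum and the antennal receptors Or22a, Or42b and Or47b were at most 0.102, 0.183 and 0.0683 CPM in all 12, so the sum said little of antennal tissue. For the list as a whole, a knockdown effect at both times (median 0.036 at ZT16) and a change with time in both genotypes (-0.23 in knockdown) were argued against. Snmp1 alone went the other way on the first of these, and the source stays open.

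The last was genes silent in 1 genotype at both times, such as Cyp12d1-d. Genes changed at least 2-fold the same way at both times numbered 122, with 23 adjacent pairs within 50 kb against a median of 8 and a highest of 20 in 10000 random sets. Such clustering may come from the genetic background of the 2 genotypes, and neighbours controlled together would also give it. The pairs were counted over all 122 genes, so they do not test the silent genes alone. Reads shared between Cyp12d1-d and Cyp12d1-p were argued against as the whole cause, since the sum of both copies was still 3.30-fold higher at the time with the smaller difference. With 1 knockdown genotype in the design, knockdown of CG5808 and background cannot be told apart for these genes. The same holds for every other difference between knockdown and control given above.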

How the results depend on the processing

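Fits without rRNA genes, without 2 libraries that stood apart (control ZT16 replicate 1 and knockdown ZT8 replicate 3) and with the Simes test were chosen after the data were seen. Of the main results under alternatives, 578 values kept their direction and side of the threshold or stayed within 1.5 times, 20 lost their call and 49 counts moved. For named genes 8280 values held, 1132 lost a call and 77 gained one, and for list tests 4382 held, 192 lost a call and 183 gained one. The 448 genes of the interaction became 276 with upper-quartile factors, 240 with no filter, 918 with DESeq2, 132 on TPM plus 1, 111 on TPM plus 0.1, 137 with the replicate block, 170 with the replicate block within time, 60 genes by a fit to transcripts and 19 to 1107 with 1 library left out. The 1671 genes of knockdown at ZT8 became 871 on the 6 libraries of the contrast, where fewer libraries set the spread, 1088 by transcripts and 673 to 2735 with 1 library left out. The 2379 at ZT16 became 1303 by transcripts and 1309 to 2759 with 1 left out. Time in control ran from 1532 to 2810, time in knockdown from 1572 to 2871, and the overlap of 670 from 373 to 1036, with 415 on the libraries of each contrast. CG5808 at ZT16 lost its call with no filter (-0.49), limma-voom (-0.50), TPM plus 0.1 (-0.53), the replicate block (-0.49) and without the 2 libraries (-0.44), and ran from -0.55 to -0.42 with 1 left out. At ZT8 tim lost its call on the contrast alone (-0.20) and with the replicate block within time (-0.20), and ran from -0.22 to -0.19. Over both times tim ran from -0.16 to -0.11. Clock genes with changed transcript usage at ZT16 numbered 0 with the replicate block, 0 with the replicate block within time and 0 to 1 with 1 library left out. At ZT8 they numbered 1 with the replicate block within time, 1 with the Simes test and 0 to 1 with 1 left out. AGO2 with time in control reversed to -0.032 on TPM plus 1 and to -0.032 on TPM plus 0.1. The median of all genes lay at -0.11 on TPM there, so AGO2 stayed above it and the sign follows from the scaling. For the antimicrobial list the direction of the camera test reversed without the 2 libraries at ZT8 (median -0.24), with time in control (-0.35) and in the interaction (-0.084). The cause was not tested for this list. Depth limits rare genes: CG5808 had 105 to 197 reads per library.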

Other observations

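The yolk protein and antimicrobial levels were picked after their values were seen, while the splits and the tests of gene length and size of the change with time were set beforehand. Yolk protein genes, made by the fat body of females, varied between libraries. Yp2 was 12585 CPM in knockdown ZT8 replicate 3 against 4802 and 5885 CPM in the other 2 of that group and 1818 to 3783 CPM in control ZT8. The female-biased list summed to 46639 CPM in that library. The sex of the flies was not given in the sources used here.

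Antimicrobial peptide and Bomanin genes, which are induced by infection, summed to 3632 CPM in control ZT8 replicate 1, 3638 CPM in knockdown ZT8 replicate 3 and 3408 CPM in control ZT16 replicate 1. The other 9 libraries held 2267 to 2613 CPM. Replicates of a group thus differed in immune transcripts.

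The number of genes changed was set against other splits of the libraries. At ZT8, 1671 genes changed and 1 of the 10 splits gave as many, the highest other being 526. At ZT16, 2379 changed and 1 of the 10 splits gave as many, the highest other being 0. With time in control, 2542 changed, in 1 of the 10 splits, the highest other being 1, and in knockdown 2488 changed, in 1 of the 10 splits, the highest other being 0. Lists called numbered 14 at ZT8 (3 of 10 splits as many, highest other 17), 14 at ZT16 (2 of 10, highest other 14), 7 with time in control (10 of 10, highest other 13) and 9 with time in knockdown (6 of 10, highest other 15). Clock genes with changed transcript usage numbered 0 at ZT8 (10 of 10 splits, highest other 1) and 1 at ZT16 (1 of 10, highest other 0). In all of these the splits were too few for a share under 0.05. For lists the other splits also called many: a median of 7 at ZT8, 9 at ZT16, 9 with time in control and 9 with time in knockdown. Chance was thus not excluded for the number of lists called in any of these comparisons.

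For comparisons over all 12 libraries 100 splits were drawn. Over both times, 1 of 100 splits, the real one, gave as many as the 3084 genes changed. The highest other gave 477, with the real groups kept at ZT16, and the median of the others was 0. This argues against chance alone for the count but does not say what separates the 2 genotypes. The overlap of 670 genes was given by 1 of 100 splits, the highest other being 0. As other splits of the ZT16 libraries called 0 genes, and genes not called cannot be shared, this says nothing on the overlap itself. Chance was not excluded for the 8 lists called over both times, as 78 of 100 splits gave as many and the highest other gave 18.

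Whether longer genes fell in knockdown was tested with the span of each gene, and no such trend was seen: Spearman rho across genes was -0.030, and 88 of 100 splits gave a value as far from 0, the highest other being 0.31. Whether changes with time were smaller in knockdown was tested over 3660 genes, and the ratio of the median absolute change was 0.995, with 1799 genes smaller in knockdown; 97 of 100 splits gave a ratio as far from 1, the highest other being 1.34. For these genes, called for the change with time averaged over both genotypes, the changes were thus of like size. A batch difference between the ZT8 and ZT16 sets would enter the changes of both genotypes. The ratio therefore cannot decide whether daily changes were damped.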
